A study of Mus musculus with 16 samples.

How the data were processed

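RNA of sorted peritoneal tumour-associated macrophages (TAMs) was measured on 16 Affymetrix mouse genome arrays. The 4 groups combined the CCR2+ or CCR2- sort label with the control or RbpjiΔEC genotype, with 4 arrays each. The values are linear probe set intensities as deposited, for 45101 probe sets. In the 8 columns labelled CCR2+ the deposited intensities had array means between 821 and 827 and medians between 234 and 249, close together as after normalization between arrays. Whether and how the authors normalized them is not given in the sources used here. In the 8 columns labelled CCR2- the intensities had means of 481 to 762 and medians of 187 to 270, farther apart. In those 8 columns 100% of the values were whole numbers after multiplication by a divisor of at most 22, within a tolerance of 0.001, against 2.58% to 2.91% in the CCR2+ columns. The sort label therefore coincides with a difference in kind between the deposited columns. The sources give no detection calls, hybridization dates or scan dates, so batches could not be tested, and the number of arrays limits the precision.

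Because the deposited values were linear, the planned step for linear values was followed: log2 transformation and quantile normalization over all 16 arrays. Of the probe sets, 34958 carried exactly 1 gene symbol, 932 carried several and 9211 were not listed in the annotation, 51 of them array controls. Those with several symbols or none were left out. Where a gene had more than 1 probe set, which held for 9012 genes, the one with the highest mean over the 16 arrays stood for it, which left 18194 genes. No intensity filter was applied. Symbols were checked against RefSeq identifiers, and 0 changed. Genomic positions were not analysed here.

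Differences were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group and a shared spread per gene, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The 5 comparisons were RbpjiΔEC minus control within each sort label, CCR2+ minus CCR2- within each genotype, and their interaction. Errors of differences are limma standard errors (SE) and errors of group means are SDs over 4 arrays, on the log2 scale. The labels do not say whether the arrays come from separate animals. If they do not, the p-values measure a spread between samples that may be technical. Single values compared outside limma, the array controls for RNA quality among them (a comparison added after the results were seen), had exact permutation tests, whose smallest two-sided p with 4 against 4 arrays is 0.0286.

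Before the data were examined, 34 gene lists of macrophage functions, markers of other cell types, and stress and ribosomal genes were fixed, as were the comparisons and most alternative settings. Of their 683 distinct members 614 were measured. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 34 lists of a comparison. Beside it stand camera with an estimated correlation and fry, which tests whether the genes of a list move on balance in 1 direction. Members were counted at adjusted p under 0.05 over all genes and adjusted over the list alone. Marker lists of B-1 and follicular B cells were written after the subset comparison had been seen.

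The rule for named genes was also fixed in advance. It takes in each comparison the 10 largest folds in each direction among called genes whose groups do not overlap, leaving out symbols made of Gm and digits or ending in Rik. It adds up to 4 called members of each list, at most 2 per direction, or else the member with the smallest p. With fewer than 10 calls it takes the 5 smallest p in each direction. It always takes Rbpj, Ccr2, Hes1, Nrarp, Ptprc, Itgam, Adgre1, Mrc1, Cd163, H2-Ab1, Vcam1, Arg1, Tnf, Il1b, Gata6 and Timd4. The text prints part of the genes that the rule takes, and that part was picked after the values were seen. Named outside the rule, after their values were seen, were H2-DMb2 and Smpdl3b in the CCR2+ genotype comparison, C1qb and Gm15934 in the CCR2- one, and C1qa, C1qc and Cd69 in the interaction. So were the B cell type genes Zbtb32, Ptpn22, Ctla4, Cd9, Cr2 and Fcer2a between the labels, and the 4 genes correlated with Ccr2.

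The method was tested on simulated data with 18194 genes, 50 of them changed at each size. In the CCR2+ genotype comparison limma recovered 46% of the genes changed by 0.5 log2 units, 86% at 1, and 100% at 1.5 and at 2, with 7 false calls. In the CCR2- genotype comparison it recovered 34%, 94%, 98% and 100%, with 3 false calls. A simulated change of −0.5 in the complement list was called in both, with 0 of the 33 other lists. The noise was drawn independently for each gene. The simulation therefore does not show how often the preset list test calls falsely where genes are correlated.

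The alternatives chosen in advance were median centring, genes above the lowest tercile of mean intensity, the mean of all probe sets of a gene, eBayes with trend and robust, array weights, adjusted p under 0.1, only the 2 groups compared, fixed and random replicate blocks, and omission of each array. For the lists, the blocked setting applied camera's preranked form to the blocked limma statistics. Added after seeing the data were quantile normalization within each label, the deposited CCR2+ values without further normalization, normexp background correction with an offset of 50, and omission of the CCR2- control arrays 1 and 3. Array 1 had the lowest mean intensity, 481, and array 3 the highest minimum, 99.9. Median centring and the omission of single arrays were also added for the lists.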

Results

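Gene expression was measured in tumour-associated macrophages (TAMs) from the peritoneal cavity of female C57BL/6N mice that carried ID8-luc cells, a mouse ovarian cancer line. The tumour cells were injected into the cavity and grew for 4 weeks. In RbpjiΔEC mice tamoxifen had removed Rbpj, the DNA-binding partner of activated Notch receptors, from endothelial cells before the tumour cells were given. TAMs were sorted as CD45+ CD11b+ F4/80+ cells and divided by CCR2, a chemokine receptor of inflammatory monocytes. The 16 arrays formed 4 groups of 4, and below "CCR2+ arrays" and "CCR2- arrays" name the deposited label only. Mean deposited intensities were 821 to 827 in the CCR2+ arrays and 481 to 762 in the CCR2- arrays. After quantile normalization a bacterial trp control, which mouse RNA should not bind, read 6.35 to 6.51 log2 units, so folds against levels near that floor understate a difference. The first principal component held 82.8% of the variance and the second 3.93%, and arrays of the same group correlated at 0.971 to 0.993, much as arrays of the same label and different genotype did (0.973 to 0.993).

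The comparison of the labels in control mice asks what separates the sorted subsets. Genes of large peritoneal macrophages, the resident macrophages of the cavity, were far higher in the CCR2+ arrays, and B cell genes were far higher in the CCR2- arrays. Gata6, the transcription factor that sets large peritoneal macrophage identity, read 12.04 ± 0.14 (SD, n = 4) in the CCR2+ and 7.78 ± 0.43 (n = 4) in the CCR2- control arrays. Timd4, a receptor for dying cells, differed by 4.39 (SE 0.22) and the complement receptor gene Vsig4 by 6.01 (SE 0.15). Cd79a, a signalling chain of the B cell receptor, read 7.65 ± 0.20 against 12.78 ± 0.18 (n = 4 each), and Ms4a1, which encodes CD20, differed by −6.46 (SE 0.18). Of 18194 genes, 3532 were higher and 3891 lower in the CCR2+ arrays at limma adjusted p under 0.05, 7423 in all or 40.8%, and 1442 and 1080 of them differed at least 2-fold.

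Of 24 measured genes of the large peritoneal macrophage list, 23 were higher in the CCR2+ arrays (median 4.49, camera adjusted p = 9.8e-24, and adjusted p = 4e-04 with an estimated correlation). Among the largest folds in this direction were Tgfb2 at 6.14 (SE 0.22), a growth factor gene, Serpinb2 at 6.07 (SE 0.17), Ltbp1 at 6.06 (SE 0.22), which encodes a TGF-beta binding protein, and F5 at 6.04 (SE 0.17), a coagulation factor gene. Fabp4, Selp, Slpi, Aspa, Ednrb and Thbs1 differed by 5.85 to 5.19. All 13 measured B cell markers were lower in the CCR2+ arrays (median −5.13, camera adjusted p = 6.62e-17, and adjusted p = 0.000595 with an estimated correlation). Fcrla differed by −6.54 (SE 0.11), the immunoglobulin light chain transcripts Igk-V21, Igk and Igkv6-15 by −6.44, −6.19 (with 1 of 4 Igk probe sets at −0.32) and −6.13, the heavy chain transcript Ighv14-2 by −5.98, the lymphocyte transcription factor gene Ikzf3 by −5.96 and the kinase gene Blk by −5.85. B3gnt5, Gimap4 and Diras2 differed by −6.04, −6.01 and −6.00. The lower groups of Serpinb2 (6.37), Fcrla (6.51), Igk-V21 (6.21), B3gnt5 (6.35) and Diras2 (6.35) read no higher than the trp control, so their folds are lower bounds and do not rank these genes.

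The markers of the sorting gate were not alike in the 2 labels. Adgre1, which encodes F4/80, read 13.25 ± 0.14 in the CCR2+ and 9.21 ± 0.24 in the CCR2- control arrays (n = 4 each), and Itgam, which encodes CD11b, read 12.71 ± 0.11 and 9.46 ± 0.08. Ptprc, which encodes CD45, differed by −0.34 (SE 0.15, limma adjusted p = 0.0846) and by 0.17 under median centring, and its other probe set by −1.83 (exact permutation p = 0.0286). Ccr2 itself was higher in the CCR2- control arrays, 9.99 ± 1.08 against 7.99 ± 1.05 (difference −1.99, SE 0.635, limma adjusted p = 0.0184, exact permutation p = 0.0571, n = 4 each). All 4 Ccr2 probe sets had the higher mean in the CCR2- arrays in both genotypes. The Ccr2 call was lost with array weights (adjusted p = 0.0651), without CCR2- control 1 (0.0716), without CCR2- control 1 and 3 (0.148), and without CCR2+ control 1 (0.0672) or 4 (0.0525). Rbpj was higher in the CCR2+ arrays by 0.92 (SE 0.15, limma adjusted p = 0.000115). Of the array controls for RNA quality, the 3' minus 5' actin signal was 0.218 in the CCR2+ and 0.365 in the CCR2- control arrays (exact permutation p = 0.0286) and that of Gapdh 0.172 and 0.106 (p = 0.486). The 18S ribosomal RNA signal was 13.1 and 11.7 as deposited (exact permutation p = 0.0857) and 12.8 and 11.9 after quantile normalization (p = 0.171).

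**Figure D1:**
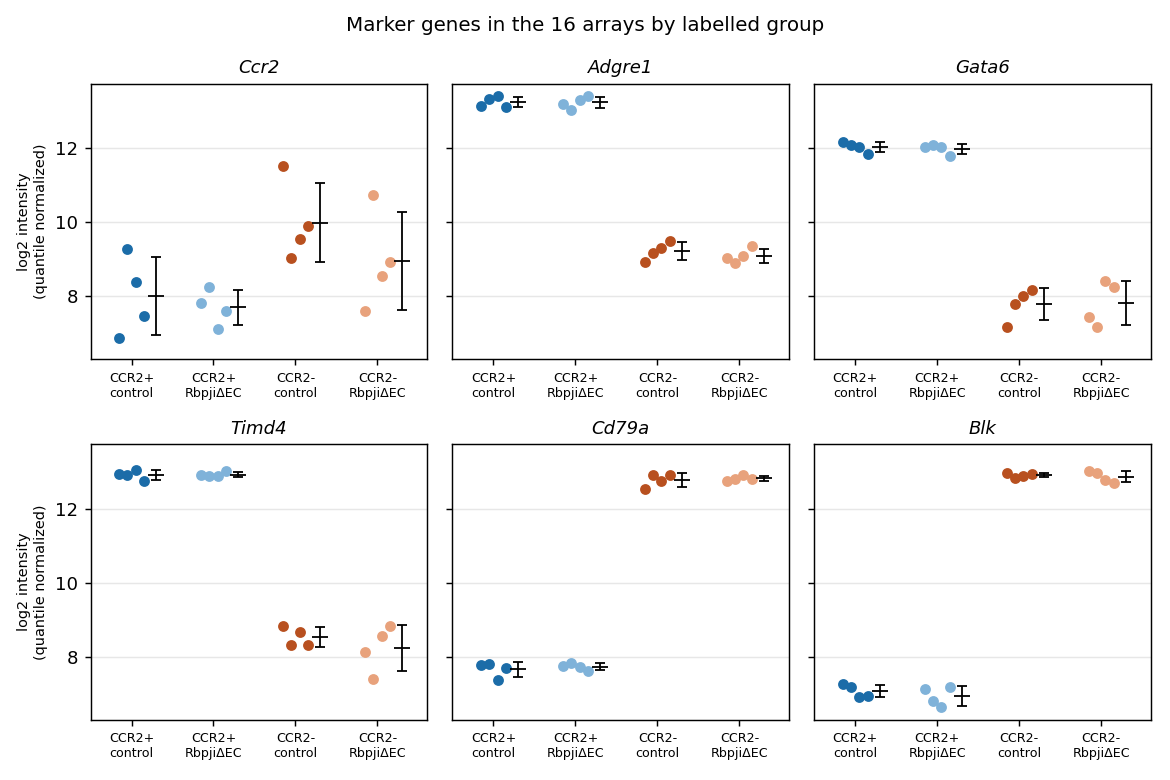
Each point is 1 array, the y axis is the quantile-normalized log2 intensity, the x axis the labelled group, and the dash with its bar is the mean ± SD of 4 arrays. Adgre1, Gata6 and Timd4 were higher in the CCR2+ arrays and Cd79a and Blk in the CCR2- arrays, while Ccr2 had its higher means, 9.99 and 8.94, in the CCR2- arrays.

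Complement genes were higher in the CCR2+ control arrays, 11 of 12 (median 2.99, camera adjusted p = 1.02e-08, and 0.00322 with an estimated correlation), among them C1qc, part of the initiator of the classical pathway, by 4.47 (SE 0.18) and Cfb by 4.45 (SE 0.17). Of 20 lipid handling genes 18 were higher (median 1.19, adjusted p = 4.05e-09, and 4e-04 with an estimated correlation), including the lipid droplet gene Plin2 by 3.20. Of 20 lysosomal genes 16 were higher and 1 lower (median 1.22, adjusted p = 1.02e-08, and 0.00494 with an estimated correlation), with the cathepsin genes Ctsl and Ctsd at 4.23 and 2.86. Of 19 efferocytosis and scavenger receptor genes 12 were higher and 3 lower (median 1.70, adjusted p = 7.02e-07, and 0.0288 with an estimated correlation), with the scavenger receptor genes Msr1 and Marco at 5.38 and 5.14. Of 27 matrix and angiogenic genes 17 were higher (median 0.79, adjusted p = 9.88e-06, and 0.00494 with an estimated correlation). MHC class II presentation genes were lower, 8 of 11 (median −1.43, adjusted p = 5.78e-06, and 0.0288 with an estimated correlation). H2-DMb2 and H2-Ob, which act in peptide loading, differed by −4.22 and −4.14, while H2-Ab1, a class II chain gene, differed by −0.29 (adjusted p = 0.471) and by 0.25 under median centring, while the lowest of its 3 probe sets, all negative, read −2.24. B cells also make class II molecules, and all 13 B cell markers were higher in the same arrays.

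The preset test also called 5 lists whose call was lost with an estimated correlation. Of 23 type I interferon genes 16 were higher and 2 lower, with Rtp4 at 3.11, Oas2 at 2.26 and Ifit2 at −1.21 (camera adjusted p = 2.33e-06, and 0.166 with an estimated correlation). Of 20 chemokine ligand genes 12 were higher and 3 lower, with Pf4 at 5.10 and Cxcl13 at 4.93 (0.00023, and 0.0779 with an estimated correlation). Of 23 alternative activation genes 12 were higher and 3 lower, with Arg1, which breaks down arginine, at 4.90, and Mgl2, a lectin gene, at −2.39 (0.000756, and 0.0792 with an estimated correlation). Of 18 iron and oxidative stress genes 10 were higher and 3 lower, with Hp at 4.61 (0.00194, and 0.0615 with an estimated correlation). Of 16 dendritic cell markers 11 were lower and 1 higher, with Dpp4 at −4.45 and Ccr7 at −3.74 (6.49e-05, and 0.0672 with an estimated correlation). Ccr7 is also among the follicular B cell markers used below, so the dendritic call is not separated from the B cell difference. Adjusted over the list alone, the counts of these 13 called lists were the same as over all genes, except 13 higher in alternative activation, 13 higher in efferocytosis, 18 higher and 1 lower in the matrix list, 12 higher in the iron list and 12 lower in the dendritic list. Of the other genes fixed in advance, Il1b, an inflammatory cytokine gene, was lower in the CCR2+ arrays, with a difference of −1.22 (SE 0.20, limma adjusted p = 0.000113). Cd163 (0.86), Vcam1 (0.30, with 1 of 3 probe sets at −0.04), Tnf (−0.15), Nrarp (−0.11), Hes1 (−0.11) and Mrc1 (−0.17, and 0.15 under median centring) did not pass, with adjusted p from 0.111 to 0.759. For Cd163, CCR2- control 1 read 9.03 and the next highest CCR2- control array 7.05. Median centring gave 4405 genes higher and 2607 lower, so the balance of directions depended on the scaling. The label coincides with a difference between the deposited columns, and the cause of the shift in balance was not tested.

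In RbpjiΔEC mice the same comparison of labels found 3290 genes higher and 3817 lower in the CCR2+ arrays, 7107 in all or 39.1% of those tested, and median centring gave 3529 higher and 2842 lower. Of the genes called, 6005 were called in the same direction in both genotypes, 2 in opposite directions, 1416 in control mice alone and 1100 in RbpjiΔEC mice alone. Across genes, which are not independent replicates, the log2 differences of the genotypes correlated at 0.975, from separate arrays. Large peritoneal macrophage genes were higher in 22 of 24 cases (median 4.59, camera adjusted p = 1.7e-24, and 0.000343 with an estimated correlation), and all 13 B cell markers were lower (median −4.94, adjusted p = 3.85e-17, and 0.000557 with an estimated correlation). Slfn4 at 6.60 (SE 0.28), Ltbp1 at 6.35, Vsig4 at 6.33, Msr1 at 6.04 and the lectin gene Clec4e at 5.87 were among the 10 largest positive folds. Igk-V21 at −6.71 (SE 0.13), Fcrla at −6.60 and Ms4a1 at −6.55 were among the 10 most negative folds. Those of Igk-V21 and Fcrla are again lower bounds in size, against 6.19 and 6.40 in the CCR2+ arrays.

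The gate markers Adgre1 and Itgam were higher in the CCR2+ arrays of RbpjiΔEC mice by 4.16 and 3.41, Gata6 by 4.18, Timd4 by 4.71, Arg1 by 4.67 and Rbpj by 1.08 (limma adjusted p = 2.22e-05). Ptprc differed by 0.12, but by −0.63 when both of its probe sets were averaged, the other one reading −1.38 (exact permutation p = 0.0286). Ccr2 read 7.69 ± 0.47 in the CCR2+ and 8.94 ± 1.32 in the CCR2- arrays (n = 4 each, limma adjusted p = 0.135, exact permutation p = 0.114), and it passed with array weights (0.0258) and without CCR2- RbpjiΔEC 1 (0.0465). Cd163, a haemoglobin scavenger receptor gene, was higher by 1.30 (limma adjusted p = 0.0325). That call was lost with array weights (0.0514) and without CCR2+ RbpjiΔEC 1 (0.108) or 2 (0.0947), or CCR2- RbpjiΔEC 1 (0.0851), 3 (0.0708) or 4 (0.0782).

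Complement genes were higher in 9 of 12 cases in RbpjiΔEC mice (C1qc by 5.22), lipid handling genes in 17 of 20, lysosomal genes in 14 of 20 with 2 lower, efferocytosis genes in 12 of 19 with 2 lower, and matrix genes in 16 of 27 with 2 lower. MHC class II genes were lower in 9 of 11 cases, H2-DMb2 by a difference of −4.26. Chemokine ligand genes were higher in 12 of 20 cases with 3 lower, and alternative activation genes in 15 of 23 with 2 lower, and these 2 lists kept adjusted p = 0.0476 with an estimated correlation. The camera adjusted p of these 8 lists lay between 1.46e-09 and 6.55e-05. Type I interferon genes were higher in 15 of 23 cases with 2 lower (2.28e-05, and 0.22 with an estimated correlation), iron genes in 8 of 18 with 3 lower (0.0124, and 0.0981 with an estimated correlation), and dendritic cell markers were lower in 9 of 16 with 1 higher (0.000224, and 0.0893 with an estimated correlation). T and NK cell markers were lower in 7 of 16 cases (0.035, and 0.097 with an estimated correlation). B cell markers were lower in the same comparison, and the dendritic and the T and NK calls were not separated from that difference. Without CCR2+ RbpjiΔEC 3 or CCR2- RbpjiΔEC 2 the adjusted p of the T and NK list was 0.0661 or 0.0555. Adjusted over the list alone, the counts differed for MHC class II, 10 lower, efferocytosis, 3 lower, matrix, 17 higher, lysosome, 15 higher, and dendritic markers, 2 higher and 11 lower. With an estimated correlation 10 of the 14 called lists held. The label coincides with a difference between the deposited columns in these mice as well.

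**Figure D2:**
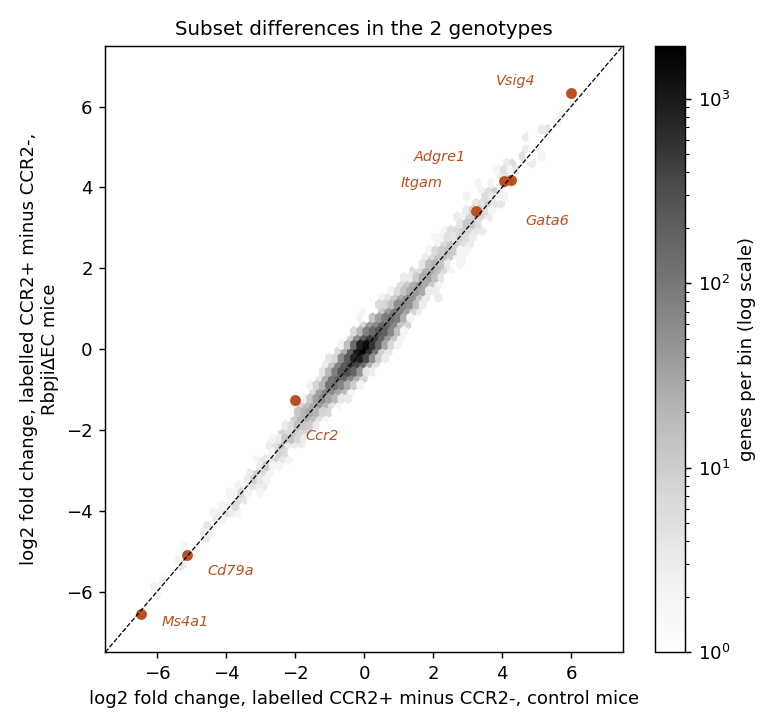
Each hexagon counts genes by their log2 difference between CCR2+ and CCR2- arrays in control mice (x axis) and in RbpjiΔEC mice (y axis), on a log colour scale, and the dashed line marks equal differences. Named genes are marked in orange, from Ms4a1 at −6.46 and −6.55 to Vsig4 at 6.01 and 6.33, and the correlation across genes was 0.975.

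The genotype comparison within the CCR2+ arrays asks how deletion of endothelial Rbpj altered these cells. The differences were small. Sec61b, a subunit of the protein channel of the endoplasmic reticulum, read 10.83 ± 0.32 in RbpjiΔEC and 11.96 ± 0.30 in control arrays (n = 4 each), a difference of −1.13 (SE 0.17, limma adjusted p = 0.0835). Acp5, an acid phosphatase gene of macrophages and osteoclasts, differed by −1.05 (SE 0.18), Fmr1nb by −0.67, Rasgrp1 by −0.42 (each adjusted p = 0.184) and Nr4a1, an early response transcription factor gene, by −0.75 (adjusted p = 0.442). In the other direction Ubl5 differed by 0.84, Cep85 by 0.83, Ms4a4d by 0.78, Il1f6 by 0.41 and Cbln2 by 0.39, with adjusted p from 0.451 to 0.532. The other probe sets of Cep85 and Ubl5 read −0.06 and 0.05, the smallest of 4 for Rasgrp1 read −0.10, and the levels of Il1f6 and Cbln2 lay at 6.37 to 6.86, near the trp control.

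All 11 measured MHC class II presentation genes had negative estimates in the CCR2+ genotype comparison (median −0.22), among them Cd74, the invariant chain gene, at −0.54 and H2-Ab1 at −0.45. So did 26 of 27 oxidative phosphorylation genes (median −0.12, Cox5b −0.28, of whose 6 probe sets 5 were negative), 17 of 19 cholesterol synthesis genes (median −0.16, Dhcr7 −0.49), 19 of 23 type I interferon genes (median −0.12, Oas3 −0.40) and 9 of 12 complement genes (median −0.11, C2 −0.58). Of 14 neutrophil markers 13 were negative (median −0.22, S100a8 −0.89), and of 9 erythroid and platelet markers 8 were positive (median 0.09, Slc4a1 0.18). Camera called 12 of the 34 lists: MHC class II (adjusted p = 0.00481, and 0.479 with an estimated correlation), oxidative phosphorylation and cholesterol synthesis (0.0113 each, and 0.575 with an estimated correlation), complement (0.0171, and 0.479 with an estimated correlation), type I interferon (0.0203, and 0.575 with an estimated correlation), neutrophil markers (0.0335, and 0.575 with an estimated correlation) and erythroid and platelet markers (0.0337, and 0.479 with an estimated correlation). The other 5 were glycolysis and hypoxia (median −0.125, adjusted p = 0.0171), MHC class I (−0.0752, 0.0171, Tap2 at −0.37), interferon gamma (−0.149, 0.0195), lysosome (−0.0896, 0.0273) and iron (−0.0959, 0.0273). Their adjusted p with an estimated correlation were 0.479, 0.517, 0.575, 0.479 and 0.479. The means of array controls also differed, without passing: the 3' minus 5' actin signal was 0.329 in RbpjiΔEC and 0.218 in control arrays (exact permutation p = 0.0857), and the 18S ribosomal RNA signal as deposited 12.3 and 13.1 (p = 0.171). RbpjiΔEC 2, at 0.205 and 13.4, lay within the control range of both. RbpjiΔEC 1, 3 and 4 lay outside it, with actin at 0.355, 0.374 and 0.384 against 0.162 to 0.275 in control arrays. Their 18S signals were 11.78, 11.82 and 12.08 against 12.13 to 13.82. The 3' minus 5' Gapdh signal was 0.162 and 0.172 in the 2 groups (exact permutation p = 0.886). Whether RNA quality bears on the list shifts was not tested.

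No single gene passed in the CCR2+ genotype comparison: limma called 0 of 18194, while 830 had an unadjusted p under 0.05, where 910 are expected by chance. Setting control 1, control 3, RbpjiΔEC 1 and RbpjiΔEC 2 against the other CCR2+ arrays gave 557 genes. The model leaves that structure in its spread, so the count of 0 does not show an absence of differences. With an estimated correlation camera called 0 lists, and fry called 0. Adjusted over the list alone, 1 gene each was lower in the complement list (C2), the inflammatory list (Il1a, −0.57) and the stress list (Nr4a1), and 2 in the monocyte list (Nr4a1 and Smpdl3b, −0.51), against 0 over all genes. Rbpj differed by 0.07 (SE 0.15), with a negative sign under array weights (−0.06) and without CCR2+ RbpjiΔEC 1 (−0.05), and 1 of its 3 probe sets was negative. Its deletion was endothelial, so the Rbpj level of TAMs does not test the genotype label. Ccr2 differed by −0.31 (SE 0.64), the Notch target genes Hes1 and Nrarp by −0.05 (SE 0.11) and 0.12 (SE 0.13, the other Nrarp probe set −0.11), Mrc1 by −0.50 (SE 0.36) and Cd163 by 0.34 (SE 0.46). Without CCR2+ control 2 Ccr2 differed by 0.12, and without CCR2+ control 4 Hes1 differed by 0.07. Single arrays decided the list count: 12 became 6 without control 1, 1 without control 3, and 6, 0 and 7 without RbpjiΔEC 1, 2 and 3. Leaving out control 2, RbpjiΔEC 2 or RbpjiΔEC 3 brought calls of Ubl5, of Ms4a4d and Sec61b, or of Acp5.

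The genotype comparison within the CCR2- arrays asks the same of the cells with that label. Complement genes had negative estimates in 10 of 12 cases (median −0.27, mean −0.36). C1qa, C1qb and C1qc, the 3 chains of the initiator of the classical pathway, differed by −1.0 (SE 0.24), −1.19 (SE 0.30) and −0.80 (SE 0.18), with limma adjusted p of 1, 1 and 0.983. C1qb has 3 probe sets, and the one used changed most, the smallest change being −0.45. C1qa read 8.79 ± 0.54 in RbpjiΔEC and 9.79 ± 0.50 in control arrays (n = 4 each). The list fell by camera (adjusted p = 2.52e-07, and 0.0189 with an estimated correlation) and by fry (adjusted p = 0.0498), and over the alternatives its adjusted p ranged from 6.47e-11 to 0.0498. Adjusted over the list alone these 3 genes fell, against 0 over all genes.

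The lectin genes Clec4d and Clec4e, receptors for microbial glycolipids, differed by −0.65 (SE 0.10, limma adjusted p = 0.15) and −0.60 (SE 0.13, adjusted p = 0.983; the other Clec4e probe set −0.03), and Focad by −0.73 (SE 0.15). Higher estimates were those of Cd69, an early activation antigen of lymphocytes, at 0.67 (SE 0.18), Sfrp4, a secreted Wnt antagonist, at 0.62 (SE 0.14), Tm9sf1 at 0.49, Slc6a2 at 0.42 (adjusted p = 0.416, with 2 of its 4 probe sets negative) and Krtap11-1 at 0.29, the others with adjusted p from 0.983 to 1. Of 14 neutrophil markers 13 had negative estimates, though 0 passed singly (median −0.36, Lcn2 −1.08, camera adjusted p = 1.15e-06, and 0.283 with an estimated correlation), and the neutrophil call was lost without CCR2- control 2 (0.0866). Large peritoneal macrophage genes (median −0.07, Fcna −0.66, adjusted p = 0.00321), chemokine ligands (median −0.11, Ccl6 −0.51, 0.0045) and the matrix list (median −0.07, Fn1 −1.06 and −0.41 in its other probe set, 0.0309) were called lower and eosinophil, basophil and mast cell markers higher (median 0.07, Mcpt4 0.32, 0.0269), each with adjusted p = 0.283 with an estimated correlation. Alternative activation genes were called lower (median −0.09, Msr1 −0.46, of whose 4 probe sets 3 were negative; 0.0334, and 0.431 with an estimated correlation). The Fn1 difference leaned on CCR2- control 1, which read 11.79, against 9.08 to 10.11 in the other CCR2- control arrays. Chil3, a chitinase-like gene of monocytes, differed by −1.13 (SE 0.49), with its RbpjiΔEC level, 6.42, at that of the trp control. The actin and 18S array controls differed by −0.0239 and 0.0262 between these groups (exact permutation p = 0.629 and 1).

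No single gene passed in the CCR2- genotype comparison either: limma called 0 genes, with 390 at an unadjusted p under 0.05. Setting the same array numbers apart gave 174 genes here, and the model again leaves that structure in its spread. Camera called 7 of 34 lists, 1 with an estimated correlation, and fry called 1. The count of 7, 1 higher and 6 lower, became 14 under median centring, 5 higher and 9 lower, 4 without CCR2- control 1 and 2 without CCR2- RbpjiΔEC 2. Without CCR2- control 2, Gm15934 was called (0.80), and without CCR2- RbpjiΔEC 4, Clec4d was called (−0.74). Without CCR2- control 1 and 3 Cd69 was called at 1.12 (limma adjusted p = 0.00211), and the chemokine ligand median was 0.00265. Rbpj differed by −0.09 (SE 0.15), and by 0.09 without those 2 arrays and 0.01 without CCR2- RbpjiΔEC 1. Ccr2 differed by −1.04 (SE 0.64), Hes1 by −0.07, Nrarp by −0.09 and Timd4 by −0.31 (SE 0.22), none of which passed. Gata6 differed by 0.03 (SE 0.24), with negative values in 4 alternatives and in 1 of its 3 probe sets (−0.07).

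**Figure D3:**
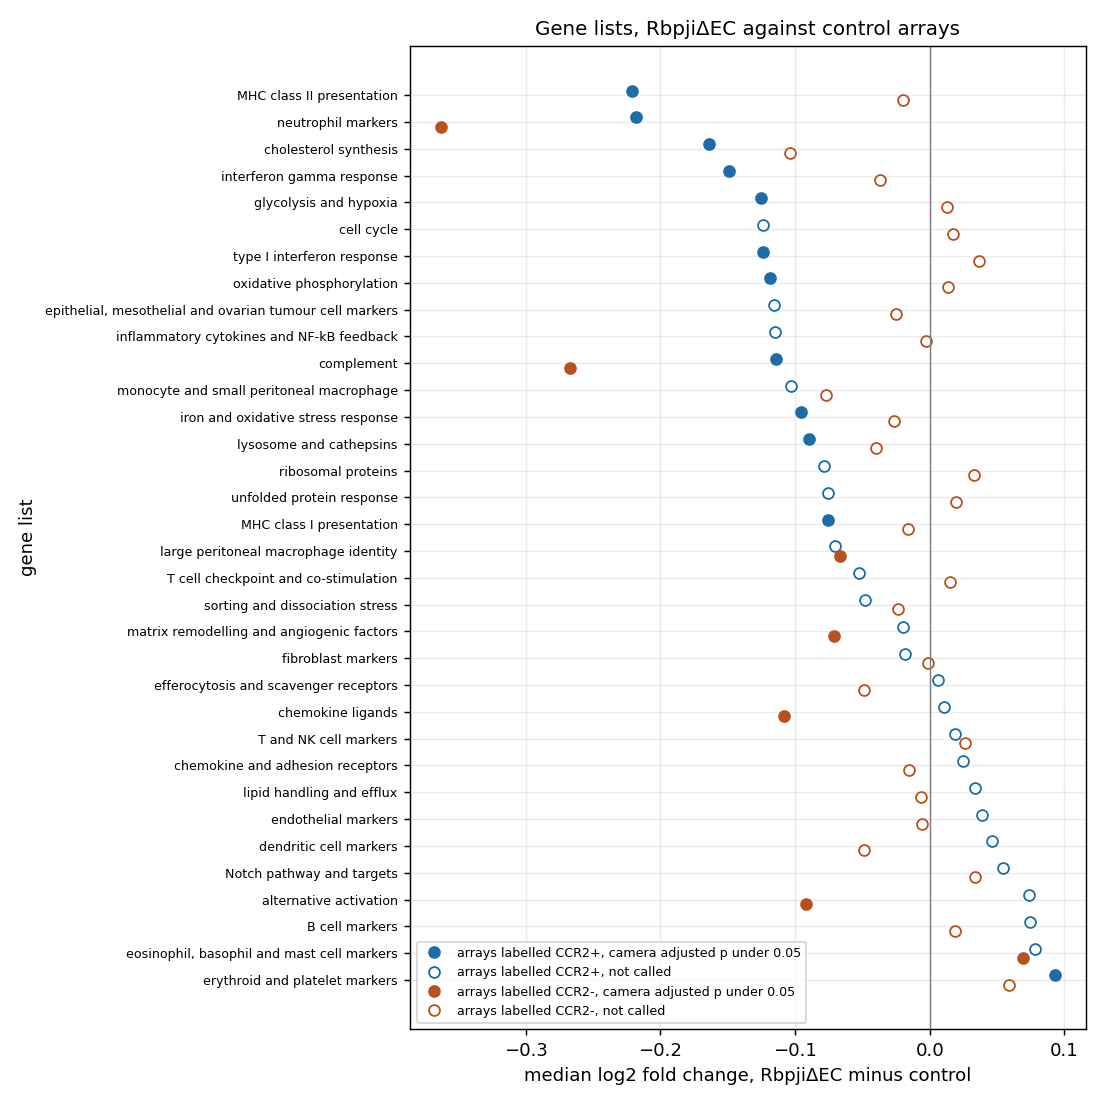
Each row of points is 1 of the 34 gene lists, and the x axis is the median log2 difference of its measured genes between RbpjiΔEC and control arrays, blue for the CCR2+ and orange for the CCR2- label. Filled points passed camera at the preset correlation, and with an estimated correlation the complement list of the CCR2- arrays, at −0.27, was the 1 that passed.

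The interaction asks whether the genotype difference itself differed between the labels, as the CCR2+ difference minus the CCR2- difference. Sec61b at −1.11 (SE 0.24), Acp5 at −1.09, Sfrp4 at −0.89, Clec4d at 0.73, Cbln2 at 0.58 and Rasgrp1 at −0.44 had the smallest p-values among the genes named here, each with limma adjusted p = 0.999. The MHC class II (median −0.177), type I interferon (−0.174) and oxidative phosphorylation lists (−0.12) were more negative in the CCR2+ arrays (camera adjusted p = 0.0483 each, and 0.701 with an estimated correlation). The complement list was not called (median 0.272, camera adjusted p = 0.342), but adjusted over the list alone 3 of its genes passed, C1qa at 0.96 and C1qc at 0.75, more negative in the CCR2- arrays, and C2 at −0.54, against 0 over all genes. Limma called 0 genes, with 555 at an unadjusted p under 0.05, and fry called 0 lists. Camera's count of 3 became 8 under median centring, 0 with normexp background correction and without CCR2+ RbpjiΔEC 1 or 2, CCR2- control 3, or CCR2- RbpjiΔEC 2, 3 or 4, 1 without CCR2+ control 1, 5 without CCR2- control 2 or CCR2- RbpjiΔEC 1, 6 without CCR2+ RbpjiΔEC 4 or CCR2- control 4, and 7 without CCR2+ control 2. Without CCR2- control 1 and 3 limma called Cd69 (−1.13, adjusted p = 0.0407), but Cd69 read 6.17 and 6.16 in the CCR2+ arrays, below the trp control, so this restates its CCR2- difference. Without those 2 arrays the oxidative phosphorylation median was 0.00443.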

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

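Chosen after the results were seen were the tests of the marker percentiles, of the B cell marker count and of the Ccr2 difference, and the counts of genes over other splits of the arrays.

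Among the arrays labelled CCR2-, B cell transcripts were high (Igk 14.34, Ms4a1 13.55, Cd79a 12.78 in control mice) and large peritoneal macrophage transcripts low, the reverse of the arrays labelled CCR2+. A different rescaling of the 2 sets of columns is argued against as the whole cause, because rescaling an array keeps its ranks: within the deposited arrays the B cell markers stood at percentile 30.2 in the CCR2+ and 98.5 in the CCR2- arrays, a median difference of 60 points (quartiles 51.8 and 70.5), and the large peritoneal macrophage genes moved by −48.1. Other differences of processing can change ranks, so the percentiles do not test them. B cells among the sorted cells stay open: 13 of 13 measured markers were at least 2-fold higher in both genotypes, but that count restates the pattern and does not test its source. A CD11b and F4/80 gate would remove most B cells. The gate genes Adgre1 and Itgam, however, were higher in the CCR2+ than in the CCR2- control arrays by 4.04 and 3.25. The intended gate alone therefore cannot exclude B cells. Exchanged CCR2 labels may also contribute, since Ccr2 differed by −1.99 in control mice (exact permutation p = 0.0571, a limma call lost in several alternatives) and by −1.26 in RbpjiΔEC mice (p = 0.114), but an exchange alone does not put B cell transcripts into sorted macrophages. A difference between 2 macrophage subsets without any B cell RNA is argued against as the whole cause, for the B cell markers. All 13 were higher in the CCR2- arrays and stood there at a median percentile of 98.5, against 30.2 in the CCR2+ arrays. How that RNA came into these arrays was not tested. A biological difference between the subsets beside it was not separately tested and stays open.

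In the arrays labelled CCR2- the mean of C1qa, C1qb and C1qc was lower in RbpjiΔEC mice by a difference of −0.998 (SE 0.357, exact permutation p = 0.0571), and the C1qb probe set of highest mean, which entered it, was also the most changed of 3, the least changed reading −0.447. A smaller share of large peritoneal macrophages stays open. The 55 genes of like level and like subset difference, within 0.5 log2 units, had a median of −0.205 (quartiles −0.369 and −0.0668). That is a smaller change than that of the C1q genes, though 46 of the 55 were lower. The test cannot decide, because genes picked for their change tend to exceed unpicked genes whatever the cause. Myeloid genes also had lower means in the RbpjiΔEC than in the control CCR2- arrays: Lyz2 11.71 against 12.39, Csf1r 9.48 against 10.16 and Itgam 9.22 against 9.46. Adgre1 read 9.08 against 9.21, while Gata6 differed by 0.03 in the other direction. Whether a smaller share of myeloid cells lies behind the C1q difference was not tested with these genes. A smaller share of Ccr2-high cells is argued against only weakly: adjusted for Ccr2 the difference was −1.0 with an SE of 0.437. The genotype stays open as a biological explanation, and these genes were picked after the comparison was seen. The complement list as a whole was not called in the interaction, so a difference confined to this label is not shown.

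The real split into genotypes gave 0 genes in the CCR2+ arrays. With a count of 0 all splits give at least as many, 35 of 35 here, so that count says nothing about chance. The highest other split gave 557 genes and set control 1, control 3, RbpjiΔEC 1 and RbpjiΔEC 2 against the other 4, which points to a structure of the samples that crosses genotype. The real split gave 12 lists there and was the only 1 of 35 splits to give as many, with 10 as the highest other. That is the smallest share that 35 splits allow, and it holds for the preset test only. The count was 0 without RbpjiΔEC 2 and 1 without control 3, and 0 with an estimated correlation and by fry. Chance is therefore not excluded for it. The CCR2- arrays also gave 0 genes, which all 35 splits match in the same way, and the highest other, 174, again set control 1, control 3, RbpjiΔEC 1 and RbpjiΔEC 2 apart. For their 7 lists 10 of 35 splits gave as many, with 11 as the highest other, so chance cannot be excluded for that count. For the labels, 1 of 35 splits gave as many genes in each genotype, the real one, with 7423 and 7107 genes against 1 as the highest other. That is again the smallest share that 35 splits allow. Splits that mix the labels also hold the label difference in the spread within their groups, which lowers their counts. The splits alone therefore do not exclude chance. The limma tests do not rest on them, and their smallest adjusted p were 3.94e-17 in control and 1.07e-17 in RbpjiΔEC mice. The 13 and 14 lists of the labels were matched by 13 and 12 of 35 splits, with 18 and 16 as the highest others. These counts cannot decide about chance, because splits that mix the labels unevenly keep part of the label difference. For the interaction 78 of 100 drawn splits gave at least the 3 lists found (highest other 15), so chance cannot be excluded for that count. Its 0 genes are matched by all 100 splits in the same empty way (highest other 185).

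At the preset correlation the interaction test called the MHC class II list (median −0.177), the type I interferon list (−0.174) and the oxidative phosphorylation list (−0.12), with camera adjusted p = 0.0483 each. With an estimated correlation the adjusted p was 0.701 each, and fry and normexp background correction called 0 lists, so a difference between the labels is not established for them.

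Of 432 groups of 4 arrays examined for 108 named genes, 22 held 1 array far from the other 3, where about 22 are expected by chance. Among the CCR2+ control arrays these were Slc4a1 in array 3 (7.059), Thbs1 in array 4 (12.48), Ctsl in array 1 (11.92), Ifit2 in array 1 (7.881), F10 in array 2 (12.3), Dtx1 in array 2 (6.743), Il5ra in array 4 (6.083) and Hdc in array 4 (11.3). Among the CCR2+ RbpjiΔEC arrays they were Oas3 in array 4 (8.619), Tap2 in array 2 (8.912), Tm9sf1 in array 3 (7.419), Cd69 in array 1 (6.239) and Cd80 in array 2 (9.351). Among the CCR2- control arrays they were Slc4a1 in array 3 (7.541), Cd163 in array 1 (9.033), Focad in array 1 (9.467), Slpi in array 4 (8.613) and Ms4a4c in array 4 (10.59). Among the CCR2- RbpjiΔEC arrays they were Ccl6 in array 1 (10.36), Ctsd in array 3 (10.54), Hp in array 1 (7.745) and Ms4a4c in array 4 (11.73).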

How the results depend on the processing

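Chosen after seeing the data were quantile normalization within each label, the deposited CCR2+ values without further normalization, normexp, omission of CCR2- control 1 and 3, and for the lists median centring and omission of single arrays. Of 2959 alternatives for the 151 single-gene results, 2905 kept direction and side of the threshold, 11 lost and 26 gained a call and 17 reversed. A gene called in neither setting counted as kept if its sign held, so the share kept says little about robustness. Of 731 for the 49 called lists 562 kept both, 167 lost the call and 2 reversed. The cause was not tested where none is given. In the CCR2+ genotype comparison the 0 genes became 1 (Sec61b) without the lowest tercile of genes by mean (fewer tested), array weights, adjusted p under 0.1 (a looser threshold) or the replicate number as a block, 2 with the mean of all probe sets (Sec61b and H2-DMb2, −0.42), and 0 to 2 without single arrays. In the CCR2- genotype comparison they became 1 (Cd69) without CCR2- control 1 and 3, and 0 to 1 without single arrays. The interaction gave 1 gene (Cd69, at background in the CCR2+ arrays) without those 2 arrays and 0 without any single array. The sources do not say whether a replicate number marks 1 animal sorted into both labels. Between the labels, correlations of same-number deviations ran from −0.0316 to 0.403 in control and from 0.0406 to 0.241 in RbpjiΔEC mice, with own numbers as mutual best matches in 2 of 4 pairs each, so pairing by animal is not settled. Between genotypes, where no animal can be shared, they ran from −0.38 to 0.151 (CCR2+) and −0.0959 to 0.194 (CCR2-). With genotype and number as a fixed or random replicate block the labels gave 7663 or 7869 genes in control and 7366 or 7591 in RbpjiΔEC mice, and the interaction 0 by either. The consensus correlation of the random block was 0.117, and it gave 12 and 7 lists in the CCR2+ and CCR2- genotype comparisons and 15 in each label comparison. The label comparisons gave 5982 to 8469 genes in control and 6348 to 8277 in RbpjiΔEC mice over all alternatives, and 6836 to 7374 and 6507 to 6864 without single arrays. Median centring gave 3529 higher and 2842 lower in RbpjiΔEC mice. Array weights lay between 0.495 and 1.98. List counts in the CCR2+ genotype comparison were 0 with an estimated correlation, 0 by fry and 0 to 10 without single arrays. In the CCR2- one they were 14 under median centring, 1 with an estimated correlation, 1 by fry and 2 to 9 without single arrays. The labels gave 8 lists with an estimated correlation and 25 by fry in control mice, 23 by fry in RbpjiΔEC mice, and 13 to 14 and 13 to 15 without single arrays. Those of the interaction were 8 under median centring, 1 without the lowest tercile of genes, 0 with the random block, an estimated correlation, fry or normexp, and 0 to 7 without single arrays. Reversed in the CCR2+ genotype comparison were Rbpj (−0.0573 with array weights; −0.0469 without RbpjiΔEC 1), Ccr2 (0.12 without control 2), Hes1 (0.0658 without control 4) and H2-DMb2 (0.0927 without control 3, 0.0338 without RbpjiΔEC 1), which without single arrays ranged from −0.0469 to 0.152, −0.681 to 0.12, −0.0961 to 0.0658 and −0.0851 to 0.0927. In the CCR2- one they were Rbpj (0.0923 without control 1 and 3, −0.175 to 0.0114 without single arrays, positive without RbpjiΔEC 1), Gata6 (−0.167 without control 1 and 3, −0.172 to 0.249 without single arrays, negative without control 1, RbpjiΔEC 3 or RbpjiΔEC 4) and the chemokine ligands (0.00265 without control 1 and 3), and in the interaction oxidative phosphorylation (0.00443 without CCR2- control 1 and 3). Between labels in control mice Ptprc (0.17), Mrc1 (0.146) and H2-Ab1 (0.253) reversed under median centring and Mrc1 (−0.469 to 0.0813 without single arrays) without CCR2- control 1, and in RbpjiΔEC mice Ptprc (−0.63) with the mean of all probe sets. Signal over background limits what dim genes show: the trp control read 6.35 to 6.51, and the lower group of Serpinb2 (6.37) and of Fcrla (6.51) in control mice lay at that level. Quantile normalization was already the main setting for the lists, so median centring took its place.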

Other observations

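Chosen after the results were seen were the tests of the B cell type and of the relation of Ccr2 to myeloid genes.

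Several lists that were not called between the labels in control mice held members called in both directions. Of 20 monocyte and small peritoneal macrophage genes 10 were higher in the CCR2+ arrays, such as the coagulation factor gene F10 at 5.29, and 7 lower, such as Napsa at −5.00 and Ms4a4c at −3.69. Of 23 Notch pathway genes 5 were higher, such as Jag1 (3.23) and Notch1 (1.91), and 4 lower, such as Dtx1 (−3.59). Of 22 T cell checkpoint genes 8 were higher, such as Nt5e (3.23, with 1 of 3 probe sets at −0.27) and Vsir (2.03), and 7 lower, such as Pdcd1lg2 (−2.04) and Cd274 (−1.41), which encode ligands of PD-1. Of 22 inflammatory genes 8 were higher and 7 lower, such as the co-stimulatory gene Cd80 (−1.93, with 1 of 4 probe sets at 0.16). Of 17 eosinophil, basophil and mast cell markers 3 were higher, such as the histamine synthesis gene Hdc (3.49), and 4 lower, such as Il5ra (−4.47), the receptor chain for IL-5. Of 16 endothelial markers 2 were higher and 2 lower, such as Pecam1 (−4.05). These 6 lists had camera adjusted p from 0.478 to 0.736.

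Counts higher and lower in the remaining lists of control mice were 1 and 6 of 16 T and NK cell markers, 2 and 0 of 14 neutrophil markers, 3 and 3 of 17 fibroblast markers, 2 and 5 of 20 epithelial, mesothelial and tumour cell markers, and 2 and 2 of 9 erythroid and platelet markers. They were 5 and 4 of 13 MHC class I genes, 8 and 3 of 18 interferon gamma genes, 8 and 5 of 19 chemokine and adhesion receptor genes, 4 and 3 of 19 cholesterol synthesis genes, 13 and 4 of 24 glycolysis genes and 8 and 1 of 27 oxidative phosphorylation genes. For cell cycle genes they were 1 and 4 of 29, for the unfolded protein response 7 and 2 of 18, for sorting stress 8 and 4 of 22 and for ribosomal proteins 1 and 3 of 20. The camera adjusted p of these lists lay between 0.0781 and 0.971. The lists not called in RbpjiΔEC mice had camera adjusted p from 0.0706 to 0.768, those in the CCR2+ genotype comparison 0.158 to 0.984, those in the CCR2- one 0.104 to 0.965 and those of the interaction 0.0796 to 0.975.

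Median, mean and test differed in sign for lists that were not called. In control mice these were the inflammatory, Notch, checkpoint, cholesterol, fibroblast and erythroid lists, and in RbpjiΔEC mice the MHC class I, inflammatory, checkpoint, fibroblast and erythroid lists. In the CCR2+ genotype comparison they were the chemokine ligand, chemokine receptor, efferocytosis and lipid lists, and in the CCR2- one the epithelial, endothelial, glycolysis and erythroid lists. In the interaction they were the inflammatory, monocyte, Notch, lysosome, stress, B cell, T and NK and fibroblast lists.

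A hypothesis is that the B cell transcripts of the CCR2- arrays came from peritoneal B-1 cells, which can carry CD11b. Of 12 measured B-1 markers 10 were called higher in the CCR2- arrays in both genotypes, among them Zbtb32 (−3.06 as CCR2+ minus CCR2- in control mice), Ptpn22 (−3.70) and Ctla4 (−2.88), and Cd9 was lower there (2.50). Of 6 measured follicular B cell markers 5 were higher too, among them Ccr7 (−3.74), Cr2 (−2.72) and Fcer2a (−2.13), so the B cell types cannot be told apart by these lists.

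Another hypothesis is that myeloid cells are the source of the Ccr2 signal in the CCR2- arrays. Over the 8 arrays Ccr2 correlated with Lyz2 at r = 0.878 (exact permutation p = 0.00394, adjusted 0.0158, rho 0.905 with exact p = 0.00456) and at 0.664 without the 2 arrays farthest from the Ccr2 median. With Csf1r r was 0.731 (exact permutation p = 0.0383, adjusted 0.0766, rho 0.714 with exact p = 0.0576), and 0.489 without those 2 arrays. With Fn1 r was 0.611 (exact permutation p = 0.11, adjusted 0.147, rho 0.548 with exact p = 0.171) and with Cd79a −0.506 (exact permutation p = 0.206, adjusted 0.206, rho −0.286 with exact p = 0.501), and 0.471 and −0.374 without them. Of these 4 relations 1 passed, so the source of the Ccr2 signal stays open. Within the 4 control arrays r was 0.98 with Csf1r, 0.999 with Fn1, 0.978 with Lyz2 and −0.879 with Cd79a, and within the 4 RbpjiΔEC arrays 0.246, −0.371, 0.949 and 0.126. The signs for Fn1 and Cd79a differed between the genotypes, so their pooled r describes neither genotype.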
